A study of Oryza sativa with 8 samples.

How the data were processed

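RNA from leaves of 2-week-old rice seedlings was sequenced in 8 libraries, 1 per group: DJ, dgp1 and glk1glk2 under control (CK) and low phosphate (LP), and ZH11 under control (CK) and without phosphate (NP). The authors deposited 1 table for the first 6 libraries (40718 genes) and 1 for the ZH11 pair (38977 genes). The deposited values have no unit in their header and were taken as FPKM made by the authors, since each nonzero value times gene length, divided by a step common to the library, was whole within 0.01 for 100% of the values. The aligner, the counting tool and the genome build were not given in the sources used here. No expression ratio was formed between libraries of different tables. Ratios formed within each table were correlated, read totals and read shares are set side by side, and ZH11 levels were used in the checks of detected genes and of genes at 0.

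The read number behind each value was recovered from that step, and read totals ran from 12525772 to 16566008. The denominator implied by the step was 0.945, 1.25, 0.783, 0.854, 1.25 and 1.29 times the recovered reads in DJ_CK, DJ_LP, dgp1_CK, dgp1_LP, glk1glk2_CK and glk1glk2_LP, and 1.01 and 1.06 times in ZH11_CK and ZH11_NP. Median-of-ratios factors of the deposited values ran only from 1.02 (DJ_LP) to 1.03 (dgp1_CK) in the 6-library table. The deposited values thus already lay near that scaling, and scaling to own read totals moves them away from it. Where the number of genes by read number had a peak (searched from 5 to 600 reads, a range set after a first search met only the spike at 1 read), the peak was taken as the reads of 1 cDNA fragment, and reads divided by the peak as estimated fragments. Where no peak was found, each read was counted as 1 fragment. A peak under 5 reads would have been missed, so those fragment numbers are upper limits. DJ_CK, glk1glk2_CK and glk1glk2_LP had a further peak at 25, 95 and 73 reads, whose origin was not tested. With these taken as 1 fragment, a choice made after the data were seen, the floor for a 1-kb gene was 5.76, 15.9 and 13.6 FPKM, and sampling alone listed 1049 genes for the DJ response, 4143 for the glk1glk2 response, 1847 and 3413 for the dgp1 and glk1glk2 effects at control and 2433 for the glk1glk2 effect on low phosphate. The number of detected genes does not tell the peaks apart, since expected over seen was 1.04, 0.909 and 0.939 with the main peak and 1.15, 1.08 and 1.12 with the further one. A floor of 3 estimated fragments, chosen after the peaks were seen in place of 3 reads, corresponded for a 1-kb gene to 11.3 FPKM in DJ_CK, 0.872 in DJ_LP, 5.30 in dgp1_CK, 0.222 in dgp1_LP, 30.5 in glk1glk2_CK, 27.1 in glk1glk2_LP, 0.189 in ZH11_CK and 0.175 in ZH11_NP. A fold against a 0 is given as at least the value over this floor. Ratio intervals (95%) are exact conditional binomial intervals over estimated fragments, which makes them approximate.

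The comparisons, gene lists, thresholds and named-gene rule were fixed before the data were examined. Each comparison used log2 of the ratio of FPKM + 1. A gene was counted as higher or lower if it differed at least 2-fold and had at least 5 FPKM in 1 of the libraries. For each of 16 gene lists, members with at least 1 FPKM were used, and the median log2 ratio was placed among those of 10000 random lists matched on mean expression (20 bins); a list was called outside below percentile 2.5 or above 97.5. The lists were phosphate starvation, phosphate transport, acid phosphatases, lipid remodelling, light harvesting, photosystem and electron transport, Calvin cycle, chlorophyll synthesis, chlorophyll breakdown, antioxidant enzymes, heat shock, jasmonate, ribosomal proteins, histones, plastid-encoded genes, and root and stem-base markers. Lists overlap: light harvesting and photosystem share 8 genes, photosystem and plastid-encoded 15, and plastid-encoded and ribosomal proteins 34. The pattern for light harvesting also took in genes with a CCT domain, so the members named LHC or CAB were summarised apart, a choice made after the values were seen. Named genes were the 10 highest and 10 lowest log2 ratios per comparison among genes with at least 10 FPKM and a symbol or described product, GLK1 and GLK2, and the 2 highest and 2 lowest members of each list. Clock genes, iron genes and genes traced across comparisons outside this rule were chosen after their values were seen.

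The number of genes that fragment sampling alone would list was simulated by drawing both libraries of a pair from their mean profile, 20 times. On simulated data with known differences, reads were recovered exactly for 100% of values in every comparison. Of 100 genes set 3-fold apart, 100 were found in each comparison except dgp1 over DJ at control, where 99 were; of 100 set 8-fold apart, 100 were found in each. In the order DJ, dgp1 and glk1glk2 low-phosphate responses, dgp1 and glk1glk2 effects at control, dgp1 and glk1glk2 effects on low phosphate, and ZH11, unchanged genes wrongly listed numbered 7, 6, 0, 3, 3, 3, 2 and 4 of 13385, 13722, 12885, 12878, 13276, 13524, 13258 and 14366. In the same order, 12, 14, 8, 12, 12, 9, 14 and 12 of 200 unshifted lists fell outside, and intervals covered the set ratio for 958, 968, 943, 960, 963, 954, 968 and 959 of 1000 genes. These simulations drew single reads, so they check the calculation and do not cover libraries of amplified fragments. The coverage of the intervals over estimated fragments was not tested. A separate simulation with 300000 fragments of 40 reads each gave a peak at 39. Alternatives were other pseudocounts, minimum values, fold limits and scalings, removal of organelle genes, Spearman correlation and, added after the data were seen, scaling to each library's own read total, fragment minimums and removal of genes at 0 in both low-phosphate or both control libraries. Tests between groups within a comparison were left out because each group has 1 library. A fit of supply over the 3 genotypes of the first table, with genotype as block (log2 of FPKM + 1, limma with a trend, Benjamini-Hochberg), was added after the data were seen; with known differences added to these libraries, labels swapped in DJ, it found 0 of 100 genes set 3-fold apart, 0 of 100 set 8-fold apart and 0 others. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, Matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.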

Results

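Leaf transcripts of rice (Oryza sativa) seedlings were measured by RNA-seq in 8 libraries, 1 for each of 8 groups. The wild type DJ, the dgp1 mutant and the glk1glk2 double mutant of that background were each grown under normal supply (CK) or on low phosphate (LP, 10 µM KH2PO4 for 6 days). A second wild-type cultivar, ZH11, was grown under normal supply or without phosphate (NP) for 24 h. The series asks how leaves of phosphate-starved plants, and of plants altered in GLK regulation, differ in their transcripts, with chloroplast photooxidative stress as its theme. GLK1 and GLK2 are Golden2-like transcription factors that activate photosynthesis and chlorophyll genes, and DGP1 is known as a repressor of GLK activity. There are no biological replicates, so each comparison describes a pair of libraries, without a p-value.

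The libraries held between 12525772 and 16566008 reads on annotated genes, but the number of distinct cDNA fragments behind them differed far more. In DJ_CK, DJ_LP, dgp1_CK, glk1glk2_CK and glk1glk2_LP the most common low read number per gene was 49, 6, 22, 182 and 146, and dgp1_LP and both ZH11 libraries had no such peak. Dividing reads by the peak gave about 281066 fragments for DJ_CK, 2761000 for DJ_LP, 723036 for dgp1_CK, 78613 for glk1glk2_CK and 85793 for glk1glk2_LP. In dgp1_LP and both ZH11 libraries each read was counted as 1 fragment (15857155 in dgp1_LP). That is an upper limit, since a peak under 5 reads would not have been found. Intervals, floors and sampling counts that use these libraries are therefore best cases. Genes with reads numbered 15005 in glk1glk2_LP and 25440 in dgp1_LP. Intervals in parentheses below are 95% intervals of a ratio over estimated fragments, and they cover counting error only. DJ_CK and both glk1glk2 libraries had a further peak at a lower read number (25, 95 and 73); taken as 1 fragment, it gave 550889, 150606 and 171586 fragments, with which these intervals would narrow and folds against a 0 in these libraries would about double. Reads of plastid-encoded genes made up 0.0764%, 0.187%, 0.107% and 0.178% of the reads in DJ_CK, dgp1_CK, glk1glk2_CK and glk1glk2_LP, and 0.00388% and 0.00467% in DJ_LP and dgp1_LP. In ZH11_CK and ZH11_NP the shares were 0.00573% and 0.00572%, so a low share was also seen under normal supply. The ZH11 table lists 127 plastid genes against 176 in the other. Ribosomal RNA took 0.0334% of the reads in DJ_CK, 0.175% in DJ_LP, 0.527% in dgp1_CK, 0.169% in dgp1_LP, 0.197% in glk1glk2_CK and 0.425% in glk1glk2_LP. Across 10507 genes, the log-scale correlation was 0.845 between DJ_CK and dgp1_CK, 0.759 between DJ_LP and dgp1_LP, 0.672 between the glk1glk2 libraries and 0.548 between the DJ libraries; genes are not independent replicates.

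**Figure D1:**
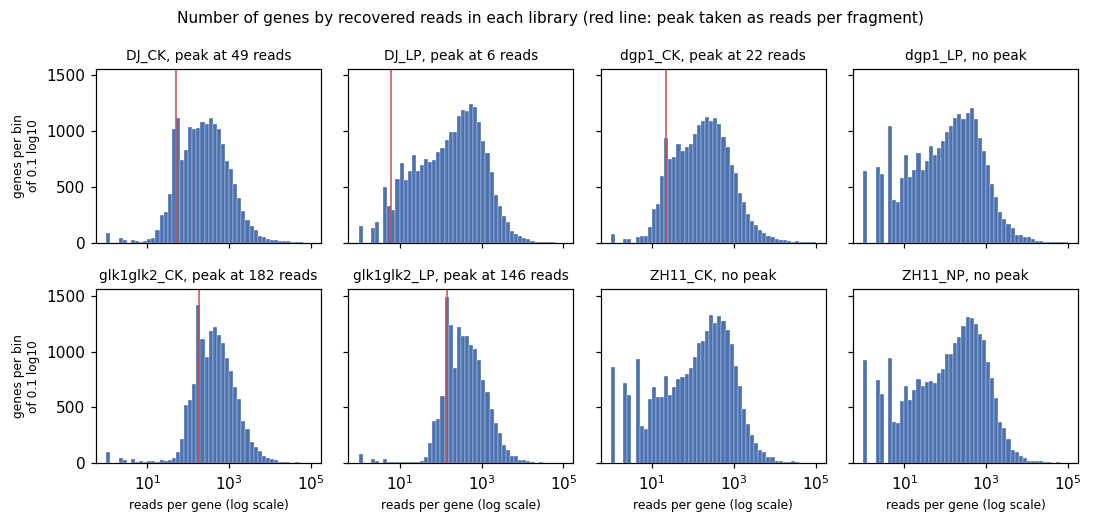
Number of genes (y axis, genes per bin) by recovered reads per gene (x axis, log scale) in each of the 8 libraries; the red line marks the peak taken as reads per fragment. The peak lies at 182 reads in glk1glk2_CK and 146 in glk1glk2_LP, and dgp1_LP, ZH11_CK and ZH11_NP have none.

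The targeted regulators GLK1 and GLK2 were measured in every library. GLK1 (Os06g0348800, chromosome 6, 14078261 to 14082203) stood at 179 FPKM in DJ_CK, 129.6 in DJ_LP, 273 in dgp1_CK, 89.2 in dgp1_LP, 40.9 in glk1glk2_CK and 49.3 in glk1glk2_LP. GLK2 (Os01g0239000, chromosome 1, 7686901 to 7693984) stood at 96.2, 86.9, 83.4, 106, 32.2 and 53.0 FPKM in the same libraries. Under normal supply GLK1 was 4.37-fold lower in glk1glk2 than in DJ (2.09 to 10.7) and GLK2 2.98-fold lower (1.46 to 6.96). On low phosphate GLK1 was 2.63-fold lower (1.43 to 5.44) and GLK2 stood at 53.0 against 86.9 FPKM, under 2-fold and with an interval that reaches 1 (1.64-fold, 1.00 to 2.89). These glk1glk2 levels rest on 7.57 to 15.8 estimated fragments per gene. GLK1 was 3.06-fold lower in dgp1_LP than in dgp1_CK (2.70 to 3.46), the largest difference of either gene between supplies. In the ZH11 table, normalized separately, GLK1 stood at 149 FPKM with phosphate and 171 without, and GLK2 at 63.5 and 73.6. The level of DGP1 was not analysed here.

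**Figure D2:**
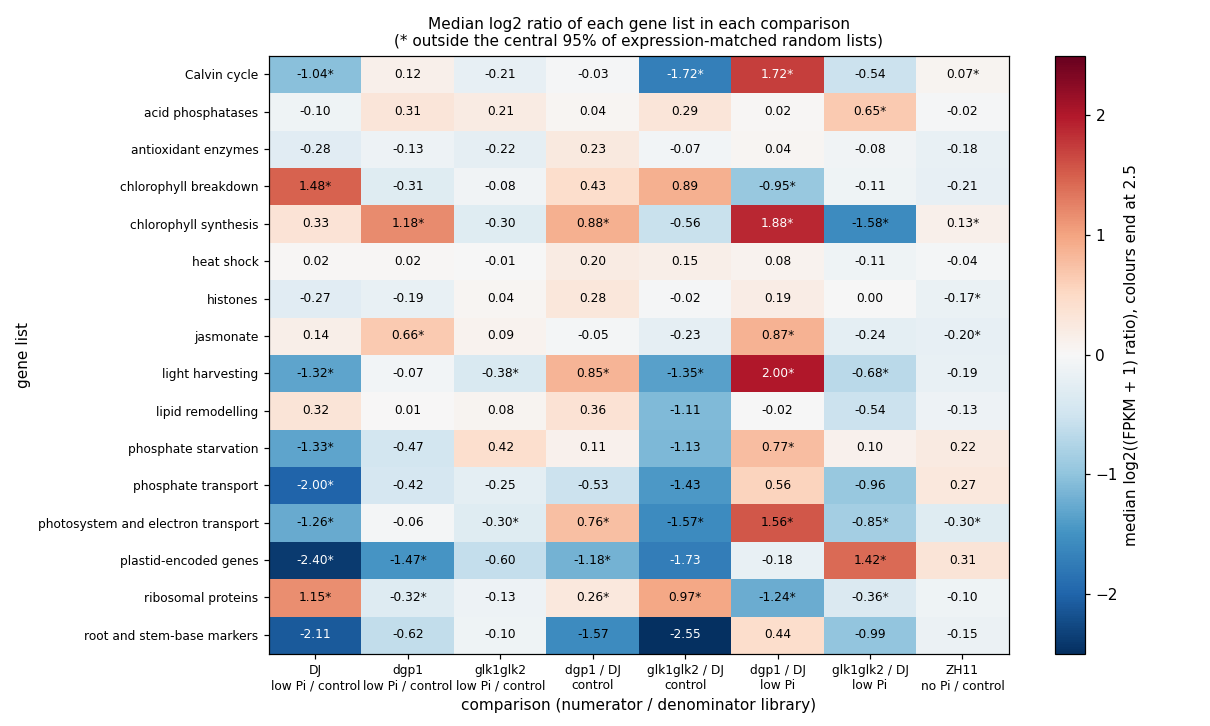
Median log2((FPKM + 1) ratio) of each of 16 gene lists (rows) in each of 8 comparisons (columns), blue lower and red higher in the first-named library; stars mark medians outside the central 95% of expression-matched random lists. Light harvesting is -1.32 in DJ and -0.07 in dgp1 for low phosphate over control, and 2.00 in dgp1 over DJ on low phosphate; the ribosomal median of 0.26 in dgp1 over DJ at control turns to -0.00395, still above the random lists, with each library scaled to its own read total.

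In wild-type DJ leaves, photosynthesis transcripts were lower on low phosphate and ribosomal protein transcripts higher. Of 27 light-harvesting genes measured, 17 were at least 2-fold lower and none higher, with a median log2 ratio of -1.32 (random lists -0.91 to 0.27). Of the 14 named LHC or CAB, 9 were lower and 0 higher. LHCB6 (chromosome 4, 22835913 to 22837163), the minor antenna protein CP24 of photosystem II, stood at 2.00 FPKM against 629, 315-fold lower (156 to 749), and PSBS2, a PsbS protein of photoprotective energy dissipation, was 23.6-fold lower (13.9 to 40.9). CAB1R stood at 4342 against 4351. Of 77 photosystem and electron transport genes, 43 were lower and 15 higher, median -1.26. Calvin cycle genes had a median of -1.04, 11 of 21 lower and 2 higher, and RBCS2, a Rubisco small subunit, was 10.2-fold lower (9.43 to 11.0). Clock genes differed beside these groups in both directions, with log2 ratios of -1.95 for LHY, -1.49 for PRR73, -1.10 for PRR37, -0.19 for PRR95, 1.74 for PRR59, 0.91 for PRR1 and 0.21 for GI; LHY is expressed towards dawn and PRR1 and GI towards evening.

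Chlorophyll breakdown genes were mostly higher in DJ_LP, 4 of 6 against 1 lower, with a median of 1.48. PAO, the pheophorbide a oxygenase, was 3.45-fold higher (2.05 to 6.33) and RCCR1, the red chlorophyll catabolite reductase, 5.56-fold higher (1.66 to 36.3), while the chlorophyll b reductase NYC1 was 2.50-fold lower (1.78 to 3.45). Ribosomal protein genes were higher as a group, 207 of 360 against 24 lower, median 1.15. The 10 highest genes included some at 0 in DJ_CK: OsPR2 (Os01g0940700), a beta-1,3-glucanase, reached 679.5 FPKM, at least 78.0-fold higher, the peroxidase POX22.3 277 FPKM, at least 32.0-fold, and Rir1b (Os10g0569800) 1064 FPKM, at least 53.1-fold. ASN1, an asparagine synthetase, was at least 46.9-fold higher. PSBR, a photosystem II subunit with a neighbouring copy that may share its reads, stood at 2656 FPKM against 11.8 (226-fold, 61.3 to 1958). OsPAL03, a phenylalanine ammonia-lyase, and the germin-like gene GLP8-12 were at least 608-fold and 266-fold lower.

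Phosphate genes in DJ_LP were lower more often than higher. The phosphate starvation list had a median of -1.33, with 7 of 12 lower and 1 higher. PECP1/ACP1, a phosphatase gene, was 8.99-fold lower (5.59 to 14.3), SPX1 stood at 11.9 FPKM against 10.5, and SPX-MFS3, a vacuolar phosphate carrier, was 2.11-fold higher (1.17 to 4.22). Of 7 phosphate transport genes, median -2.00, 4 were lower and 2 higher: the transporters PT1 and PT8 were 2.94-fold (1.68 to 5.66) and 3.71-fold (1.56 to 11.7) higher. With only members at 10 FPKM or more, 3 genes, that median was 1.52. Plastid-encoded genes had a median of -2.40 (-5.22 with pseudocount 0.1 and -0.97 with pseudocount 5), 21 of 24 lower and 2 higher, beside the plastid read shares of 0.00388% and 0.0764% (0.00573% in ZH11_CK, under normal supply). The photosystem I gene psaC stood at 0 against 643 FPKM, at least 181-fold lower. Lists within the range of random lists were acid phosphatases (-0.10), antioxidant enzymes (-0.28), chlorophyll synthesis (0.33), heat shock (0.02), histones (-0.27), jasmonate (0.14), lipid remodelling (0.32) and the root and stem-base markers (-2.11, 2 genes).

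Counted over 15357 genes with at least 5 FPKM in one library, 3551 were at least 2-fold higher in DJ_LP and 3727 lower. Sampling of the estimated fragments alone, with no difference between libraries, listed 2155 genes on average, and scaling each library to its own read total, which shifted the genes by 0.40 log2, gave 5141 higher and 2800 lower.

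**Figure D3:**
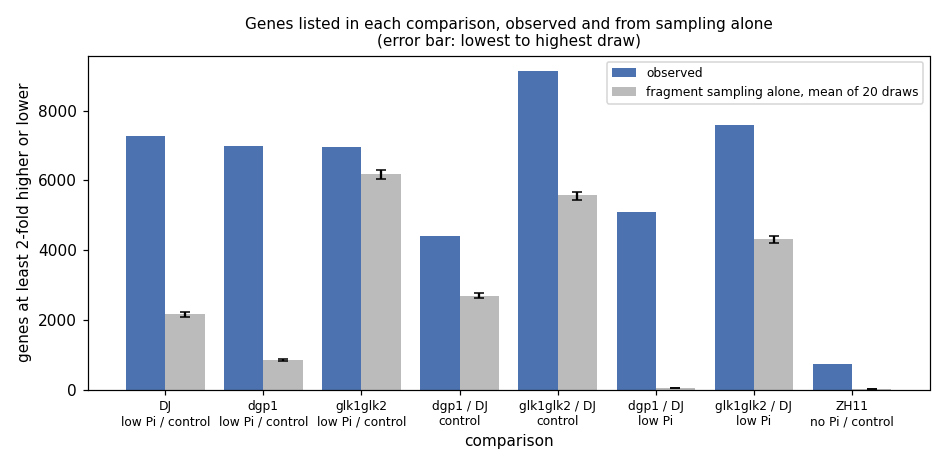
Genes at least 2-fold higher or lower (y axis) in each of the 8 comparisons (x axis): observed (blue) and from fragment sampling alone (grey, mean of 20 draws; error bars, lowest to highest draw). Sampling alone reaches 88.7% of the observed number for low phosphate over control in glk1glk2 (59.5% with the further peaks) and 0.735% for ZH11.

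In the dgp1 mutant, low phosphate left light-harvesting transcripts near their control level as a group, and chlorophyll synthesis and jasmonate transcripts were higher. The light-harvesting median was -0.07, with 3 genes higher and 7 lower of 28, and the 14 genes named LHC or CAB had a median of 0.61. CAB2R was 5.30-fold higher (5.07 to 5.55) and LHCB6 69.6-fold lower (57.7 to 84.4). CAB2R and CAB1R are near-identical copies, so their values are uncertain. Chlorophyll synthesis genes were higher, 8 of 13 and none lower, median 1.18; the protochlorophyllide reductase PORA was 47.4-fold higher (18.8 to 169) and the magnesium chelatase subunit CHLD 6.14-fold (2.99 to 15.2). Clock genes stood beside these groups at log2 ratios of -1.76 for LHY, -1.14 for PRR73, -0.22 for PRR37, 0.81 for PRR95, 1.00 for PRR59, 0.82 for PRR1 and 0.41 for GI. Jasmonate genes had a median of 0.66, 18 of 47 higher and 8 lower, led by the JAZ repressor genes OsJAZ4, 54.8-fold higher (32.6 to 101), and TIFY11A, at 350.3 FPKM against 6.82.

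Of the 10 highest genes in dgp1_LP, the nicotianamine synthase genes OsNAS1 and NAS2 reached 1677 and 568 FPKM and were at least 439.7-fold and 135-fold higher than in dgp1_CK, where both were at 0. OsIRO2, a transcription factor of the iron deficiency response, was at least 584-fold higher, the metal transporter gene NRAMP1 at least 206-fold and the mitochondrial iron-regulated gene OsMIR at least 112-fold. In DJ, OsIRO2 and NRAMP1 also stood higher on low phosphate, at 97.6 and 27.4 FPKM against 0 in DJ_CK. Root markers stood beside this group: the silicon transporter LSI1 was at 34.5 FPKM in dgp1_LP and 53.6 in dgp1_CK, and RCC3 was at 0 in both. OsRNS5, of the T2 ribonuclease family, was at least 213-fold higher and the cell-wall enzyme gene OsXTH10 was 584-fold higher (111 to 17749). PT1 stood at 370.1 FPKM against 17.3, 21.4-fold higher (13.7 to 35.7), but the phosphate transport list had a median of -0.42 within the random range, 2 of 7 higher and 3 lower. The phosphate starvation list had a median of -0.47 within the random range. Plastid-encoded genes were lower, 14 of 20 against 3 higher, median -1.47 (-3.13 with pseudocount 0.1 and -0.60 with pseudocount 5), beside plastid read shares of 0.00467% and 0.187% (0.00573% in ZH11_CK, under normal supply), and psaC was at least 294-fold lower. Ribosomal protein genes had a median of -0.32, 33 of 359 higher and 63 lower. OsTPP7, a trehalose-6-phosphate phosphatase gene, and OsMFT1 were at least 937-fold and 476-fold lower, and the cytosolic ascorbate peroxidase APX1 was 35.4-fold lower (29.9 to 41.9). Of 15600 genes tested, 3738 were higher and 3234 lower, against 852 from sampling alone, and own-total scaling shifted the genes by 0.12 log2.

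In glk1glk2, much of the difference between the 2 supplies was within what so few fragments give. Of 15007 genes tested, 3492 were at least 2-fold higher on low phosphate and 3474 lower, and sampling alone listed 6175 on average, 88.7% of that number. With the further read peaks of these libraries, at 95 and 73 reads, taken as 1 fragment, sampling alone listed 4143, 59.5%. Light-harvesting genes had a median of -0.38, 6 of 26 lower and 1 higher, and photosystem genes -0.30. These were the only lists of 16 outside the random range. The 13 light-harvesting genes named LHC or CAB had a median of -0.35, with 1 lower and 0 higher, so most of the lower members were not of that group. CAB2R stood at 213 FPKM against 215, and LHCB6 at 54.0 against 30.7 (1.76-fold, 0.420 to 9.32). PT8 stood at 81.4 FPKM against 58.7 (1.39-fold, 0.702 to 2.82), and the chlorophyll breakdown genes NYC3 and PAO at 1.70-fold (0.839 to 3.63) and 2.01-fold (0.791 to 5.65). Clock genes had log2 ratios of -0.21 for LHY, 0.22 for PRR73, -0.10 for PRR37, 1.34 for PRR95, -0.25 for PRR59, -1.30 for PRR1 and 0.05 for GI. For most of the genes with the highest and lowest ratios the interval included 1, as for SDH8B, at 0 against 94.6 FPKM and with a ratio interval of 0 to 1.36.

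The light-harvesting and ribosomal responses of DJ were not seen at that size in either mutant, with the glk1glk2 response limited by its few fragments. Gene by gene, the low-phosphate log2 ratio in dgp1 minus that in DJ had a median of 1.07 over 28 light-harvesting genes, with 16 at least 1 log2 more positive in dgp1 and 3 more negative. For chlorophyll synthesis the median difference was 1.61, for the Calvin cycle 1.47, for jasmonate 0.83, for ribosomal proteins -1.40 and for chlorophyll breakdown -1.78. In glk1glk2 minus DJ it was 0.81 for light harvesting, 1.71 for phosphate starvation genes (1.05 with pseudocount 5) and -1.26 for ribosomal proteins. Over all genes, 4310 were more positive and 3850 more negative in dgp1 than in DJ of 17337, and 5732 and 5802 of 17958 in glk1glk2. With 1 library per group these differences between responses carry no test.

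Under normal supply, the dgp1 mutant had more light-harvesting, photosystem and chlorophyll synthesis transcript than DJ. Light-harvesting genes had a median of 0.85, with 11 of 28 higher and 1 lower, and photosystem genes 0.76, 27 of 72 higher and 12 lower. Of the 14 genes named LHC or CAB, 5 were higher and 1 lower. Chlorophyll synthesis genes had a median of 0.88, 6 of 13 higher and 1 lower, the higher ones including the magnesium chelatase subunit CHLI, 4.21-fold (1.49 to 16.6). The single lower light-harvesting gene, LHCB1.3, a copy of the CAB group with uncertain reads, was 3.28-fold lower (1.48 to 7.57). The plastid fructose bisphosphatase gene cpFBP was 5.07-fold higher (4.04 to 6.43) and PRXQ, a thioredoxin-dependent peroxidase of the chloroplast, 2.96-fold (2.06 to 4.38). Clock gene log2 ratios were 0.16 for LHY, 0.34 for PRR73, 0.47 for PRR37, -0.10 for PRR95, 1.05 for PRR59, 0.32 for PRR1 and 0.55 for GI. GLK1 was 1.53-fold higher (1.20 to 1.96). Plastid-encoded genes had a median of -1.18 (-1.51 with pseudocount 0.1 and -0.60 with pseudocount 5), 17 of 26 lower and 6 higher, although the plastid read share was 0.187% in dgp1_CK and 0.0764% in DJ_CK. Among the lowest genes, OsXTH10 stood at 1.53 FPKM against 163 (107-fold lower, 19.4 to 3299), OsRNS5 was at least 14.0-fold lower and the lipid transfer protein gene OsLTP1.5 at least 8.08-fold lower. Several of the 10 highest were ribosomal and small nucleolar RNAs, beside rRNA shares of 0.527% in dgp1_CK and 0.0334% in DJ_CK; a large-subunit rRNA gene, ENSRNA049465125, stood at 227 FPKM against 3.28. Ribosomal protein genes had a median of 0.26, which turned to -0.00395 with each library scaled to its own read total; that scaling shifts all genes alike, and the list stayed above the range of random lists.

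For dgp1 over DJ under normal supply, 2342 of 14557 genes were higher and 2053 lower, against 2680.2 from sampling alone. Own-total scaling shifted the genes by -0.27 log2 and turned that split to 1485 higher and 2771 lower.

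The double mutant had less photosynthesis transcript than DJ under normal supply. Light-harvesting genes had a median of -1.35, 17 of 27 lower and 3 higher; of the 14 genes named LHC or CAB, 11 were lower and none higher. LHCB6 was 20.5-fold lower (7.37 to 87.1). Photosystem genes had a median of -1.57, 46 of 72 lower and 11 higher, with PsbY, a photosystem II subunit, at least 4.75-fold lower. Calvin cycle genes had a median of -1.72, 13 of 19 lower and 1 higher, with the Rubisco small subunit gene RbcS5 at least 10.3-fold lower. RBCS2, which may share reads with it, was 13.0-fold lower (9.22 to 18.8). CHLH, a magnesium chelatase subunit, stood at 4.39 FPKM against 102, 23.2-fold lower (5.96 to 225), but the chlorophyll synthesis list as a whole, median -0.56, lay within the random range. Clock genes differed beside these groups too, with log2 ratios of -1.55 for LHY, -1.93 for PRR73, -2.28 for PRR37, -1.44 for PRR95, 0.92 for PRR59, 1.08 for PRR1 and -0.62 for GI, the lowest levels among them resting on few fragments. LHY and PRR1 differed in opposite directions, while GI went the way of LHY. A time-of-day difference between these libraries was not tested and stays open.

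Higher in glk1glk2_CK were ribosomal protein genes, 163 of 339 against 54 lower, with a median of 0.97. SGR, the magnesium dechelatase of chlorophyll breakdown, stood at 145 FPKM against 10.3, 14.1-fold higher (4.58 to 59.8). DIP3, described as a xylanase inhibitor, stood at 6616 FPKM against 19.97, 331-fold higher (159 to 838). ST1 and RNRS2, small subunits of the ribonucleotide reductase that makes deoxynucleotides, were at 0 in DJ_CK and at least 119-fold and 54.0-fold higher. The phosphate transporter PT8 was 8.50-fold higher (2.93 to 30.2), but its list, phosphate transport, had a median of -1.43, 4 of 7 lower and 1 higher. The phosphate starvation list had a median of -1.13, 7 of 12 lower and 0 higher. Both lists lay within the random range. Of 15533 genes tested, 4256 were higher and 4865 lower, against 5575 from sampling alone. Own-total scaling shifted the genes by 0.41 log2 and gave 5645 higher and 3924 lower, and 517 and 895 remained countable where a level worth 10 fragments in the shallower library was required.

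On low phosphate, the dgp1 mutant had more light-harvesting, Calvin cycle and chlorophyll synthesis transcript than DJ, and less ribosomal protein transcript. Of 27 light-harvesting genes, 24 were higher and none lower, median 2.00 (random lists -0.26 to 0.88), including all 14 genes named LHC or CAB. CAB2R stood at 14755 FPKM against 655, 22.5-fold higher (21.7 to 23.4), and LHCB1.3, of the same group of copies, at 4991 against 6.83. Chlorophyll synthesis genes had a median of 1.88, 11 of 13 higher and none lower; PORA was 20.7-fold higher (16.0 to 27.3) and GUN4, an activator of magnesium chelatase, 10.3-fold (8.18 to 13.2). Calvin cycle genes had a median of 1.72, 12 of 20 higher and 0 lower, with phosphoglycerate kinase PGK 11.4-fold higher (10.6 to 12.3), and 51 of 76 photosystem genes were higher and 7 lower. Clock genes beside these groups had log2 ratios of 0.35 for LHY, 0.69 for PRR73, 1.36 for PRR37, 0.90 for PRR95, 0.31 for PRR59, 0.23 for PRR1 and 0.75 for GI. Chlorophyll breakdown genes had a median of -0.95, 3 of 6 lower and none higher, with NYC1 7.51-fold lower (6.00 to 9.42).

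**Figure D4:**
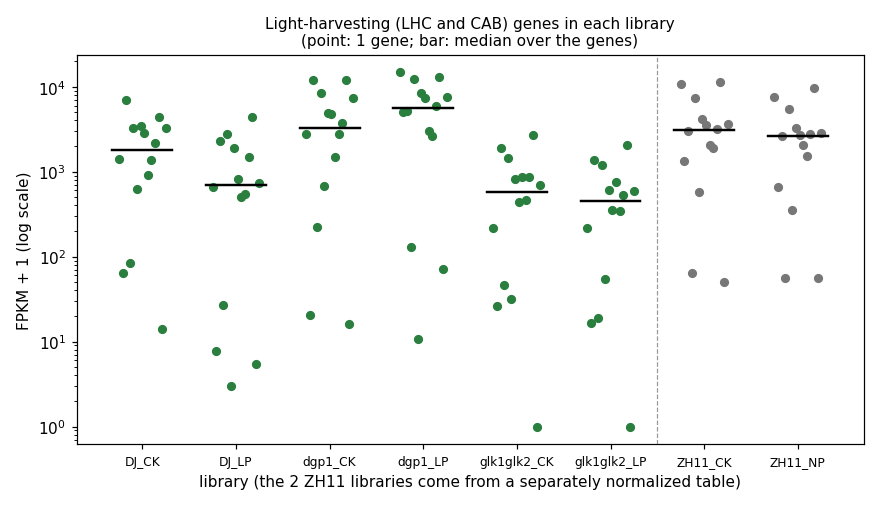
FPKM + 1 (y axis, log scale) of the 14 light-harvesting genes named LHC or CAB in each of the 8 libraries (x axis); points are genes and bars medians over them. All 14 are higher in dgp1_LP than in DJ_LP, and 11 of 14 are at least 2-fold lower in glk1glk2_CK than in DJ_CK.

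Jasmonate genes and the named genes OsNAS1 and OsMIR were also higher in dgp1_LP than in DJ_LP. OsNAS1 stood at 1677 FPKM against 0.174, which rests on 5 reads, under 1 estimated fragment (ratio interval 1517 to 716883), OsMIR at 561 against 0.413 (1359-fold, 318 to 18896), and LSI1, the root marker, at 34.5 against 25.1. Jasmonate genes had a median of 0.87, 22 of 46 higher and 5 lower, with OsJAZ4 221-fold (144 to 356) and TIFY11A 258-fold higher (109 to 815), and Lox2_Os_1, a lipoxygenase gene, 51.9-fold lower (35.0 to 79.8). The terpene synthase gene OsTPS29 was 393-fold higher (186 to 1019). PT1 was 5.22-fold higher (4.76 to 5.74), PECP1/ACP1 6.35-fold (4.75 to 8.67), and the phosphate starvation list had a median of 0.77, 5 of 12 higher and 1 lower, which lay within the random range when only members of at least 10 FPKM were used. Ribosomal protein genes were lower, 219 of 360 against 27 higher, median -1.24. Among the 10 lowest genes, the peroxidase POX8.1 was 207-fold lower (142 to 316), OsPR1b 164-fold (85.7 to 362) and OsPR2 (Os01g0940700) 59.4-fold (51.4 to 68.8). GLK2 stood at 106 against 86.9 FPKM, a difference whose direction turned with own-total scaling. This pair had the most fragments of the 6-library table, and 3097 of 14814 genes were higher and 1987 lower against 44.5 from sampling alone. The 44.5 is a lower limit, since each read of dgp1_LP was counted as 1 fragment. Own-total scaling shifted the genes by -0.55 log2 and gave 1918 higher and 4066 lower.

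On low phosphate, the double mutant had less chlorophyll synthesis and photosystem transcript than DJ. Chlorophyll synthesis genes had a median of -1.58, 8 of 12 lower and 1 higher, with CHLI at 0 against 21.4 FPKM (ratio 0 to 1.07). Photosystem genes had a median of -0.85 and light-harvesting genes -0.68, 11 of 27 lower and 7 higher. Of the 14 genes named LHC or CAB, 7 were lower and 2 higher. PSBS2 was 27.5-fold higher (14.5 to 52.0). PSBR was at 0 against 2656 FPKM, at least 60.7-fold lower, and was also at 0 in glk1glk2_CK and dgp1_CK. OsPR1, POX8.1 and the chitinase gene Oschib1, all at 0, were at least 15.2-fold, 15.3-fold and 12.5-fold lower. SGR and NYC1 were 4.86-fold (2.92 to 7.74) and 4.22-fold (2.82 to 6.14) higher, the sucrose exporter gene SWEET13 392-fold (108 to 2714) and the lipoxygenase gene OsLOX1 48.5-fold (26.8 to 89.7). Clock gene log2 ratios were 0.19 for LHY, -0.22 for PRR73, -1.28 for PRR37, 0.08 for PRR95, -1.08 for PRR59, -1.14 for PRR1 and -0.79 for GI. Acid phosphatases, which release phosphate from organic esters, had a median of 0.65, 8 of 18 higher and 5 lower, with OsPAP10c 8.40-fold (3.95 to 16.5). Plastid-encoded genes had a median of 1.42 (3.88 with pseudocount 0.1 and 0.42 with pseudocount 5), 7 of 11 higher and 3 lower, beside plastid read shares of 0.178% and 0.00388%, and rpoA was at least 166-fold higher. Ribosomal protein genes had a median of -0.36. Of 15352 genes tested, 3610 were higher and 3987 lower, against 4305 from sampling alone.

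In ZH11, 24 h without phosphate left most transcripts within 2-fold, with 5 of 16 gene lists outside the random range. HB2, a non-symbiotic haemoglobin gene (chromosome 3, 6624980 to 6626080), stood at 115 FPKM against 2.11, 54.3-fold higher (36.9 to 83.4), and the nitrate reductase genes OsNIA1 and OsNR1 were 63.3-fold (41.7 to 101) and 24.2-fold (20.5 to 28.9) higher. SPX-MFS2 and SPX-MFS3 were 5.32-fold (4.41 to 6.46) and 2.75-fold (2.54 to 2.97) higher, whereas PT1 was 2.61-fold (2.42 to 2.81) and SPX1 1.73-fold lower (1.37 to 2.18); the phosphate starvation list, median 0.22, lay within the random range, and outside it with pseudocount 0.1 (0.33) and with members of at least 10 FPKM (0.36). Rab16A, a dehydrin responsive to abscisic acid, was 12.4-fold higher (6.54 to 26.5). The PR10 genes RPR10b and RSOsPR10, neighbours that may share reads, were 31.8-fold lower (26.4 to 38.6) and at 26.5 against 591 FPKM, the thaumatin-family gene OsPR5 31.4-fold (23.9 to 42.0) and the salt-responsive lectin gene OsJRL 21.6-fold (20.3 to 22.9). OsGABA-T, an aminotransferase of gamma-aminobutyrate, was 346-fold lower (159 to 945), OsLTP2.9, a lipid transfer protein gene, 43.2-fold (35.6 to 52.9) and PORA 3.94-fold (3.84 to 4.03).

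Gene lists in ZH11 moved little. Photosystem genes had a median of -0.30 (random lists -0.18 to 0.01), jasmonate genes -0.20 and histones -0.17, while chlorophyll synthesis and Calvin cycle genes stood at 0.13 and 0.07, all outside the random range. The jasmonate median lay within it with pseudocount 5 and with members of at least 10 FPKM. Light-harvesting genes had a median of -0.19 within the random range. The 14 of them named LHC or CAB had a median of -0.33, with 0 higher and 1 lower, and were not placed among random lists. The stay-green gene SGR was 2.78-fold lower (2.43 to 3.19) and the catalase gene CATC stood at 607 FPKM against 276. Of 15002 genes tested, 242 were at least 2-fold higher and 479 lower, against 5.30 from sampling alone, in libraries of 15612820 and 16059486 reads without a peak of repeated fragments.

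The low-phosphate response of DJ overlapped with that of dgp1 and showed almost no correlation with those of glk1glk2 or ZH11. Across 13620 genes the log2 ratios of DJ and dgp1 had a Pearson correlation of 0.596 and a Spearman correlation of 0.469; 1227 genes were higher in both, against 589 from the product of the shares, and 1627 lower in both against 590.3. LHCB6 and psaC were among those lower in both. DJ_LP and dgp1_LP also shared low plastid read shares, 0.00388% and 0.00467%, and 143 genes at 0 in both that were abundant in both controls. The plastid share of ZH11_CK, under normal supply, was nearly as low (0.00573%). Without genes at 0 in both libraries of a supply the correlation was 0.523 (DJ low-Pi response with dgp1 low-Pi response). With glk1glk2 the Pearson correlation was 0.0259 over 12406 genes, in a response where sampling alone gave 88.7% of the listed number (59.5% with the further peaks), and with the ZH11 response -0.0443 over 12518, where the Spearman correlation was 0.0161. Comparing the glk1glk2 effect under normal supply with the DJ response gave 0.594, but both use DJ_CK, and unchanged groups simulated against that shared library gave 0.569 (0.538 with the further peaks); the covariance was 2.14 against a simulated 0.7005 (0.336). In that comparison 1590 genes were higher in both against 479 from the product of the shares and 649.6 in that simulation. Pairs without a shared library gave 0.198 for the glk1glk2 effect under normal supply with the dgp1 response and -0.379 for the glk1glk2 effect on low phosphate with the dgp1 response. The DJ and dgp1 libraries of the same supply resembled each other (0.845 at control, 0.759 on low phosphate). Traits they share, of whatever origin, push the first value up and the second down, and by how much was not tested. The glk1glk2 effects under the 2 supplies correlated at 0.245, with 1144 genes higher in both against 685 and 1299 lower in both against 864, and the dgp1 effects under the 2 supplies at -0.032.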

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

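Of the tests below, those of detected genes against estimated fragments, of a few genes taking most of the reads and of time of day were set before their results; the others, and the limits that picked the group differences, were chosen after the values were seen.

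Gene lists were picked out where the low-phosphate medians of 2 genotypes had opposite signs and lay at least 1 log2 apart, and none of these differences was tested, since each group has 1 library. For dgp1 against DJ these were Calvin cycle genes (0.12 against -1.04, a difference of 1.16), chlorophyll breakdown genes (-0.31 against 1.48, -1.79) and ribosomal proteins (-0.32 against 1.15, -1.47). For glk1glk2 against DJ they were chlorophyll breakdown (-0.08 against 1.48, -1.56), phosphate starvation (0.42 against -1.33, 1.75) and ribosomal proteins (-0.13 against 1.15, -1.29). For glk1glk2 against dgp1 it was chlorophyll synthesis (-0.30 against 1.18, -1.48).

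Genes with few reads were scarce in 5 of the 6 DJ, dgp1 and glk1glk2 libraries. A minimum value set by the authors is argued against by 268 genes with 1 to 9 reads in glk1glk2_CK, and fewer sequenced reads by a lowest total of 80.2% of that of ZH11_CK. Few distinct cDNA fragments, each amplified into many reads, fits: detected genes lay within 20% of the number expected from the estimated fragments in 6 of 6 libraries, a test that assumes the ZH11_CK profile. DJ_LP and dgp1_LP lay within 20% at their full read number too, so only 4 libraries could have come out otherwise, and for DJ_LP the test decides nothing. What made the fragment numbers low stays open, and no biological explanation was tested.

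Of 5100 genes at 20 FPKM or more in both DJ_CK and dgp1_CK, 158 had no reads in DJ_LP and 150 none in dgp1_LP, and 143 had none in both, 30.8 times the product of the shares, which argues against random loss of fragments. Loss of organelle transcripts is argued against by the 2.1% of them on an organelle genome. Of the nuclear ones, 10.7% (6.12% to 17.1%) overlap an annotated gene on the opposite strand, against 9.81% of all nuclear genes at that level, an overlap tried with several limits first. That argues against counting by strand at annotated overlaps, but transcripts missing from the annotation were not covered. Of the 119 found in the ZH11 table, 111 had 5 FPKM or more in both ZH11 libraries. A difference in library preparation or plant material between these low-phosphate libraries and the rest cannot be told apart from a response to 6 days of low phosphate that needs GLK, since the genes kept their level in glk1glk2 (median -0.17) and ZH11 (-0.17), as either would give.

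The light-harvesting list was lower on low phosphate in DJ (median -1.32) and not in dgp1 (-0.07). Its 14 members named LHC or CAB had medians of -1.33 and 0.61. The tests below used the whole list, which also holds genes with a CCT domain. With each library scaled to its own read total, the gene-by-gene median difference was 0.81 (1.07 as reported). The difference of the list medians, added later, was 0.98 (1.25 as reported). That scaling, a test that replaced median-of-ratios scaling, shifts the genes of a response about alike by a known amount (0.40 log2 in DJ, 0.12 in dgp1). It shows only that the choice between these 2 scalings does not account for the difference. Without the 100 most abundant genes of each library the differences were 0.94 gene by gene and 0.69 between the list medians. That removal also took the list members among those genes and left 15, so these values do not cover the most abundant light-harvesting genes. How many of the 15 are named LHC or CAB was not counted, so these values may rest largely on other list members. With all 28 kept and the same rescaling they were 1.14 and 1.31, which argues against a few abundant genes shifting the scale. A time-of-day difference is argued against by LHY, PRR1 and GI, which lay within 2-fold between dgp1_LP and DJ_LP (largest log2 ratio 0.75), although PRR37 was 2.59-fold higher. That covers this pair only: between supplies LHY was lower in both DJ (-1.95) and dgp1 (-1.76), so a difference in time of day between control and low phosphate stays open. Library preparation stays open, as does a biological difference through DGP1, which remains a hypothesis found and weighed on the same libraries.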

How the results depend on the processing

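The settings scaled to own read totals, with a fragment minimum or without genes at 0 in both libraries of a supply, and the fit with genotype as block, were chosen after the data were seen; the others were planned. Leaving out columns, a replicate block and DESeq2 were not run, since the tables hold 1 column per sample and FPKM. Numbers of lists outside the random range stayed within 1.5 times in 40 of 40 alternatives, and list medians kept direction and side in 588 of 640 (3 weaker, 7 stronger, 42 with the other sign); the weaker ones were jasmonate, ZH11 non-Pi response (-0.20; -0.10 with pseudocount 5 and -0.07 with members of at least 10) and phosphate starvation, dgp1 effect, low-Pi (0.77; 0.66 with members of at least 10). The stronger ones, outside the random range only then, were lipid remodelling (-1.11; -1.50 with pseudocount 0.1, -1.07 with own totals) and plastid-encoded genes (-1.73; -4.30 and -1.67) for the glk1glk2 effect at control, and in ZH11 phosphate starvation (0.22; 0.33 with pseudocount 0.1, 0.36 with members of at least 10) and plastid-encoded genes (0.31; 1.13 with members of at least 10, 2 genes). Signs turned in 42 (reported value to alternative), and all but 3 kept their side of the range. Own-total scaling turned 23, among them the ribosomal median below. In the DJ response: acid phosphatases (-0.10 to 0.28), antioxidant enzymes (-0.28 to 0.12) and histones (-0.27 to 0.12). In the dgp1 response: light harvesting (-0.0674 to 0.0550) and photosystem (-0.0584 to 0.0313). In the glk1glk2 response: heat shock (-0.0126 to 0.0284). In dgp1 over DJ at control: acid phosphatases (0.0423 to -0.22), antioxidant enzymes (0.23 to -0.0299), heat shock (0.20 to -0.0483), histones (0.28 to -0.0290) and phosphate starvation (0.11 to -0.14). In glk1glk2 over DJ at control: antioxidant enzymes (-0.0698 to 0.33), histones (-0.0200 to 0.38) and jasmonate (-0.23 to 0.17). In dgp1 over DJ on low phosphate: acid phosphatases (0.0232 to -0.50), antioxidant enzymes (0.0416 to -0.46), heat shock (0.0835 to -0.41), histones (0.19 to -0.35) and root and stem-base markers (0.44 to -0.0842). In glk1glk2 over DJ on low phosphate: histones (-0.000205 to 0.0496). In ZH11: acid phosphatases (-0.0228 to 0.0333) and heat shock (-0.0407 to 0.0166). Members of at least 10 FPKM, so fewer genes, turned 18, among them the phosphate transport median below. In the DJ response: heat shock (0.0215 to -0.14) and jasmonate (0.14 to -0.22). In the dgp1 response: heat shock (0.0205 to -0.0720), lipid remodelling (0.0118 to -0.23) and phosphate transport (-0.42 to 1.04). In the glk1glk2 response: heat shock (-0.0126 to 0.000669), lipid remodelling (0.0774 to -0.0509) and phosphate transport (-0.25 to 0.11). In dgp1 over DJ at control: phosphate starvation (0.11 to -0.0797). In glk1glk2 over DJ at control: histones (-0.0200 to 0.0946) and phosphate transport (-1.43 to 0.94). In dgp1 over DJ on low phosphate: lipid remodelling (-0.0193 to 0.0000176). In glk1glk2 over DJ on low phosphate: antioxidant enzymes (-0.0823 to 0.11), heat shock (-0.11 to 0.14) and histones (-0.000205 to 0.57). In ZH11: acid phosphatases (-0.0228 to 0.19) and phosphate transport (0.27 to -1.06). Median-of-ratios scaling turned 1, acid phosphatases in ZH11 (-0.0228 to 0.0217). List medians of the differences between responses stayed in 117 of 128, and 11 moved, with pseudocount 0.1 or 5. For dgp1 minus DJ: plastid-encoded genes (1.13; 1.68 and 0.57), root and stem-base markers (1.80; 3.37 and 0.91) and phosphate transport (1.24; 0.71 with 5). For glk1glk2 minus DJ: plastid-encoded genes (2.23; 4.79 and 0.83), root and stem-base markers (2.06; 3.64 and 1.16), phosphate transport (-0.44; -1.41 with 0.1) and phosphate starvation (1.71; 1.05 with 5); the cause was not tested. Gene counts stayed within 1.5 times in 50 of 82 and moved in 32, none of them with median-of-ratios scaling. Gene counts as reported were 7278 (DJ low-Pi response), 6972 (dgp1 low-Pi response), 6966 (glk1glk2 low-Pi response), 4395 (dgp1 effect, control), 9121 (glk1glk2 effect, control), 5084 (dgp1 effect, low-Pi), 7597 (glk1glk2 effect, low-Pi) and 721 (ZH11 non-Pi response). At least 4-fold gave 3645, 3607, 4254, 1715, 5294, 1766, 4262 and 132 in that order, and a value of at least 20 gave 3428, 3403, 2594, 1525, 4408, 2795, 3371 and 268, where fewer genes pass by construction. Without a low-value filter, more genes were tested: 11492 (DJ response), 10933 (dgp1 response), 7775 (dgp1 effect at control), 12050 (glk1glk2 effect on low phosphate) and 1299 (ZH11). Pseudocount 5 gave 2873 for the dgp1 effect at control and 323 for ZH11; the cause was not tested. A level worth 10 fragments in the shallower library, with fewer genes tested, gave 2800, 4464 and 234 for the responses, 1129 and 1412 for the effects at control and 945 for glk1glk2 on low phosphate; its first form, 10 fragments in 1 library, gave 268 for the glk1glk2 response and 1691 and 2618 for the effects at control. The ribosomal median of dgp1 over DJ at control turned from 0.26 to -0.00395 with own-total scaling (shift -0.27), still above the random lists. That of phosphate transport in the DJ response reversed from -2.00 to 1.52 with members of at least 10 FPKM, 3 genes; the cause was not tested. For shared responses, DJ low-Pi response with ZH11 non-Pi response, the correlation of -0.0443 reversed to 0.0161 by Spearman and was -0.0647 with values of at least 20; for shared responses, DJ low-Pi response with dgp1 low-Pi response, 0.596 became 0.469 by Spearman, 0.670 with values of at least 20, 0.554 with pseudocount 5 and 0.523 without genes at 0 in both libraries of a supply; the cause was not tested. A fit of supply over the 3 genotypes with genotype as block (limma, 2 residual degrees of freedom) passed 0 of 19121 genes at an adjusted p of 0.05 and 1668 at an unadjusted p of 0.05; differences between the responses of the genotypes count as noise in it. With labels swapped in DJ it also found 0 of 100 genes set 8-fold apart, so its 0 says nothing about whether genes differ. In 10 of the 10 splits of the 6 libraries as many genes passed, too few splits for a share under 0.05; the real value was 0 and the highest other 0. Depth limits glk1glk2 most, where 3 fragments of a 1-kb gene equal 30.5 and 27.1 FPKM.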

Other observations

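The iron genes were gathered after their values were seen, and no explanation of them was tested.

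The iron genes gathered here stood at least 2-fold higher in dgp1_LP than in DJ_LP, and IRO2, IRO3, NRAMP1 and NAAT1 also stood higher in DJ_LP than in DJ_CK. The nicotianamine synthase genes NAS1 and NAS2 were at 1677 and 568 FPKM in dgp1_LP and 0.174 and 0.615 in DJ_LP, and at 0 in DJ_CK, dgp1_CK and both glk1glk2 libraries. IRO2, a regulator of the iron deficiency response, was at 1301 in dgp1_LP, 97.6 in DJ_LP and 0 in DJ_CK, IRO3 at 333, 52.1 and 2.77, NRAMP1 at 518, 27.4 and 0, NAAT1, an aminotransferase of phytosiderophore synthesis, at 638, 114 and 4.40 and MIR at 561, 0.413 and 0. The transporter genes YSL15 and TOM1, which serve iron uptake with phytosiderophores, were at 33.2 and 12.8 in dgp1_LP and at 0 in DJ_LP. YSL2 was at 21.2 against 3.78 in DJ_LP and 13.5 in glk1glk2_CK, DMAS1 at 69.2 against 23.8 in DJ_LP, and the iron transporter gene IRT1 at 2.89 against 0 in DJ_LP. For YSL2, TOM1 and IRT1 the libraries with fewer fragments do not show which library was highest. Root markers did not follow them: LSI1 was at 63.2 FPKM in DJ_CK, 25.1 in DJ_LP, 53.6 in dgp1_CK and 34.5 in dgp1_LP, and RCC3 was at 0 except for 6.55 in DJ_CK.

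DIP3, a xylanase inhibitor gene, stood at 19.97 and 53.5 FPKM in DJ_CK and dgp1_CK and at 1616, 1084, 6616 and 6275 in DJ_LP, dgp1_LP, glk1glk2_CK and glk1glk2_LP. The ribonucleotide reductase gene RNRS2 was at 402.5 and 515 in the glk1glk2 libraries, 12.6 in DJ_LP, 5.51 in dgp1_LP and 0 in both other controls.

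The reverse of the genes lost in both low-phosphate libraries was also seen: of 4796 genes at 20 FPKM or more in both DJ_LP and dgp1_LP, 42 had no reads in either control, against 1.02 from the product of the shares. Of the 143 genes lost, 60.8% were described as hypothetical, against 14.5% of all genes at that level, and 105 had 5 FPKM or more in glk1glk2_LP.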
